A study of Mus musculus with 2 samples.

How the data were processed

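Total RNA of the heart of B6NCrl mouse embryos at embryonic day 11.5 was measured by RNA sequencing in 2 libraries, numbered replicate 1 and replicate 2 in the labels and made from 2 separately recorded biosamples, pools of hearts of both sexes. Per the labels, RNA was extracted with the mirVana kit, 10 ng with a size range above 200 (no unit is given) went into each library, spike-in RNAs were added, and a general protocol for SmartSeq is attached. The labels give 109 embryos for the pool of replicate 1, and no number for that of replicate 2. There is 1 group, so no comparison between conditions was made.

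The authors deposited a gene table and a transcript table for each library. Per the file headers, these hold expected counts (estimated reads per gene or transcript, not normalized, and not whole where reads were shared), TPM (transcript abundance corrected for length, scaled to a fixed sum over all rows of a library, spike-in rows included), posterior means of both, and the percent of a gene's abundance in each of its transcripts. The README texts deposited beside them name the mm10 assembly and annotation release M4. The aligner, the quantifier and their versions are not given in the sources used here, nor is the strand setting, so a gene and its antisense partner cannot be told apart from these counts. Effective lengths in the files lay 99 bases below the gene length in 100% of single-transcript genes over 200 bases, which raises the TPM of very short genes. Genes with near-identical copies had their reads divided by the authors' model.

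Both libraries have the same 43346 mouse genes, 97 spike-in rows and 26248 tRNA rows. Symbols, gene types and coordinates were taken by gene identifier from GENCODE M21 on GRCm38, the same assembly as mm10 with a later annotation than that of the files. Of the mouse genes, 42462 (98.0%) matched, and they held 99.8% of the counts in mouse genes in either library. Expected counts summed to 37617442 in replicate 1 and 27642765 in replicate 2, of which mouse genes held 34447169 and 25261719. Where 0 counts were listed, the limit was set at 3 counts, which is 0.0871 CPM of mouse gene counts in replicate 1 and 0.119 in replicate 2. Intervals of shares are 95% Wilson intervals, and all intervals and limits cover counting error only. A chi-square of rounded counts over 16621 genes came to 24.8 per gene between the libraries, so they are not copies of 1 library. That they are biological replicates rests on the labels, which give separate biosamples with the same donor identifier, and the SD over the 2 libraries has no other basis.

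Levels are given as the mean and SD of TPM over the 2 libraries. A gene was counted as detected at a TPM of 1 or more in both. For 31 gene lists chosen before the data were examined, the median TPM of the members was taken in each library, and the median of their mean TPM was placed among 10000 random lists of the same size drawn from protein-coding genes with a count. For 40 gene pairs, the log2 ratio of TPM was taken in each library, and a pair was called apart when both libraries had the same gene higher and the mean exceeded the 95th percentile of the replicate difference over 10000 random pairs matched by expression decile. With 2 libraries the smallest p of an exact two-sided sign-flip test is 0.5, so no p is given for levels, pairs or isoforms.

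The libraries were compared with Pearson's r and Spearman's rho across genes on log2(TPM + 1), for genes at a TPM of 1 or more in at least 1 library. Expected counts were rounded to whole numbers for all count methods. The biological coefficient of variation was estimated with edgeR 4.0.16 in R 4.3.3 (TMM scaling, intercept alone, genes with a mean count of 10 or more), which leaves 1 residual degree of freedom per gene. Each gene with a summed count of 20 or more was compared between the libraries by an exact two-sided binomial test, with the share under no difference from TMM effective library sizes and Benjamini-Hochberg adjustment over 16621 genes. A gene was called at an adjusted p under 0.05 and a fold of 2 or more, with 0.5 added to each count. This test compares 2 libraries and covers counting error alone. The median log2 ratio of each list (members with a summed count of 20 or more) was set against 10000 random lists of the same size, drawn with replacement from the same expression deciles, and called outside when beyond their central 95%. A further 6 lists (yolk sac endoderm, hepatic genes not on the fixed list, gut and septum mesenchyme, the ribosomal DNA locus, nuclear-retained long noncoding RNAs and ribosomal proteins) were chosen after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

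The binomial comparison was tested on simulated libraries with counting noise alone and 200 changed genes among 16621. It recovered 92 of 100 genes changed 3-fold and 96 of 100 changed 5-fold, and called 2 unchanged genes. The real libraries had more spread than counting noise (chi-square of 24.8 per gene), so the 2 false calls give no error rate for them. Simulated coefficients of variation of 0.05, 0.1 and 0.2 were estimated as 0.0493, 0.1 and 0.199.

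Genes named in the text are the 20 protein-coding and 10 other nuclear genes with the highest mean TPM, the 4 highest members of each list with any member needed for its lowest value, the genes of the pairs, the 10 largest folds in each direction among called genes with a mean count of 100 or more, the fixed isoform genes at a mean TPM of 10 or more, and the lists of sex-linked genes and of RNAs without a poly(A) tail in full. A gene named outside this rule is said to be chosen after its values were seen. Alternatives were other TPM thresholds, posterior means, other scalings (total count, DESeq2 1.42.0 size factors, spike-ins), other count filters and pseudocounts, another fold, an edgeR exact test with the common dispersion, DESeq2 dispersions, and each library alone. A few members of the fixed lists, pairs and isoform genes are not reported here. The tRNA rows, the intervals of TPM in the files and the phiX row (0 counts in both libraries) entered no comparison. Of the list genes, 3 of the erythroid list and 1 of the replication-dependent histones had no match by symbol and were left out.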

Results

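Hearts of B6NCrl mouse embryos at embryonic day 11.5, when the looped heart tube is forming chambers, were profiled by total RNA sequencing in 2 libraries from pools of both sexes that the labels record as separate biosamples, under the same donor identifier. Replicate 1 (a pool of 109 embryos) had 37617442 expected counts and replicate 2 had 27642765. The design has a single group, so the questions it answers are which genes the tissue expressed, at what level relative to each other, and how closely the pools matched. Levels are in TPM (length-scaled transcript abundance), as mean ± SD over the 2 libraries (n = 2), unless stated otherwise. Coordinates are on mm10.

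The most abundant nuclear protein-coding transcripts came mainly from globin and contractile genes. Hbb-y, an embryonic beta-like globin (chromosome 7, 103851749 to 103853216), stood highest at 27100 ± 3140 TPM, followed by the alpha globin gene Hba-a2 at 15510 ± 1930. Actc1, the cardiac alpha actin (chromosome 2, 114047282 to 114053548), came next at 9392 ± 340. They were followed by the globins Hba-x (8288 ± 1460), Hba-a1 (7239 ± 986) and Hbb-bh1 (6081 ± 475), then the myosin light chains Myl7 (5787 ± 381) and Myl2 (5027 ± 50.8). Nppa, the atrial natriuretic peptide gene (chromosome 4, 148000722 to 148002079), reached 4229 ± 264. Hba-a1 and Hba-a2 are near-identical copies, so the split of reads between them is uncertain. The other genes among the 20 highest were Tpm1, Tnnt2, Tnni1 and Myl3 of the sarcomere, Atp5b of the mitochondrial ATP synthase, the glycolytic enzyme gene Gapdh, the imprinted gene Mest at 3143 ± 138, the ferritin gene Ftl1, and Ppia, Eef1a1 and Actb. The 10 most abundant mouse genes of any kind, mitochondrial and noncoding ones included, together held 12.5% ± 1.2 of TPM in mouse genes. The 8 globin genes held 8.01% ± 0.936.

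Of the nuclear genes that are not protein-coding, Gm42418 was the highest at 8698 ± 3160 TPM. It lies beside Gm26917 (1960 ± 632 TPM) on chromosome 17 between 39843013 and 39848788, where the assembly has ribosomal DNA sequence. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle, were listed at 4305 ± 51.6 TPM each, an equal split of shared reads. Malat1, a nuclear long noncoding RNA, had 4124 ± 1490 TPM, with 5180 in replicate 1 and 3067 in replicate 2. Gm28437, Gm29216 and Gm28661, unprocessed pseudogenes on chromosome 1 between 24613189 and 24616197, ranged from 2479 to 7388 TPM. They are nuclear copies of mitochondrial sequence, so the source of their reads is uncertain, as are the levels and shares of the mitochondrial genes. Gm10123, a processed pseudogene, had 2751 ± 64.1. Gm22133 (2762 ± 120 TPM) is annotated as a microRNA of 109 bases, lies within Ftl1, and had 812 and 539 counts.

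A total of 13354 genes, 12118 of them protein-coding, were at 1 TPM or more in both libraries. Protein-coding genes held 95.1% ± 1.02 of the counts in mouse genes, lincRNA genes 2.14% ± 0.728 and genes of the mitochondrial chromosome 2.18% ± 0.321. In the single libraries, the lincRNA share was 2.66% in replicate 1 (95% Wilson interval 2.65 to 2.66) and 1.63% in replicate 2 (1.62 to 1.63). Most of this share lay in Gm42418 and Gm26917, annotated as lincRNA genes but located at ribosomal DNA sequence. Together they held 2.15% of counts in replicate 1 and 1.25% in replicate 2.

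Genes of the sarcomere, the contractile unit of muscle, were expressed at a median of 474 ± 25.3 TPM, with 28 of 29 members detected and 23 at 100 TPM or more in both libraries. Actc1, Myl7, Myl2 and Tpm1 led the list, and Myom2, a protein of the mature M-band, was lowest at 0.17 ± 0.127. Of the 31 lists, 13 had a median above the central 95% of random lists of protein-coding genes of the same size, the sarcomere list among them. Among contractile isoform pairs, Myh7 exceeded Myh6, the myosin heavy chain of the adult mouse ventricle, 1.91-fold (log2 ratio of Myh6 to Myh7 -0.93 ± 0.113). The slow skeletal troponin Tnni1 exceeded the cardiac Tnni3 2.13-fold, Tnnt2 exceeded Tnnt1 15.1-fold, and Tnnc1 exceeded the fast skeletal Tnnc2 3910-fold, Tnnc2 having 15 and 4 counts. That log2 ratio of 11.93 was 11.07 with posterior mean TPM, 10.47 with 1 added to each TPM, and 11.19 and 12.67 in the single libraries. Actc1 was 22.4-fold above the skeletal actin Acta1 and 7.62-fold above the smooth muscle actin Acta2. These pairs, and 35 of the 40 pairs in all, were apart by more than the replicate spread. Atrial-type Myl7 and ventricular-type Myl2 (log2 ratio 0.20 ± 0.08) were not, nor were Myl4 and Myl3 (-0.13 ± 0.02). The replicate spread does not cover errors that both libraries share, such as that of the length correction.

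**Figure D1:**
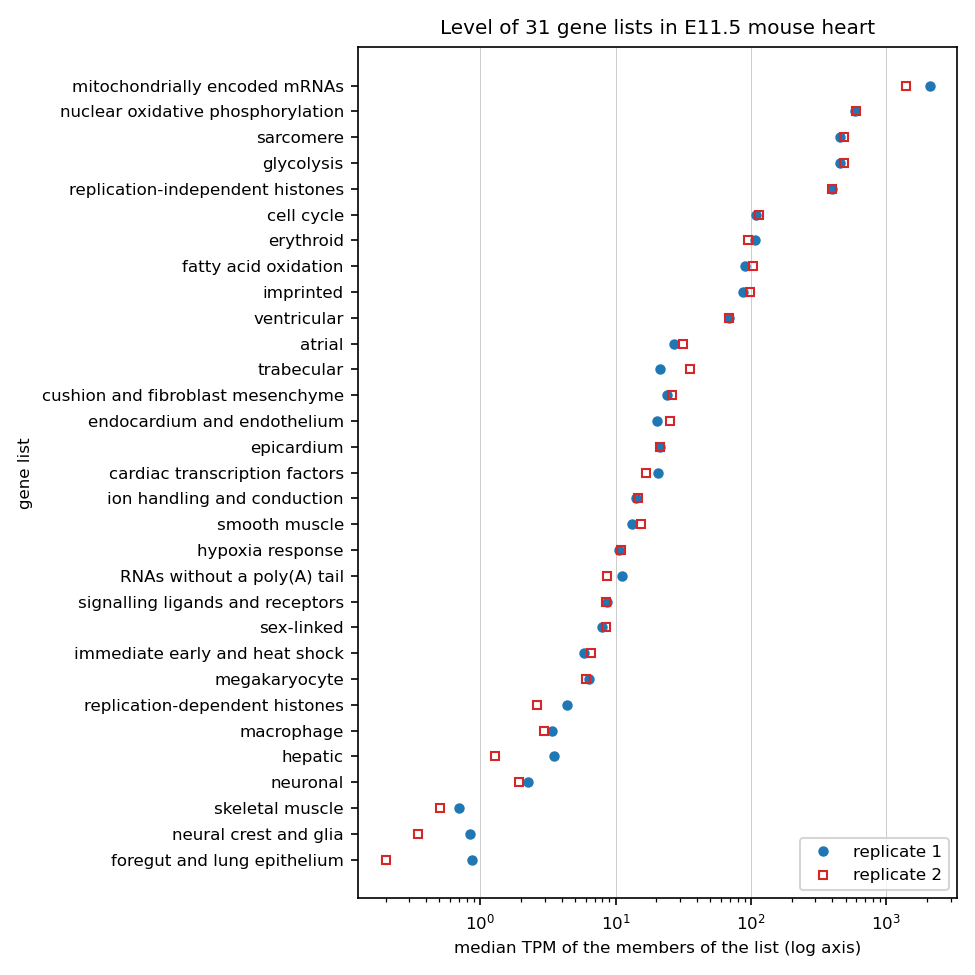
Median TPM (log axis) of the members of each of the 31 gene lists, with filled circles for replicate 1 and open squares for replicate 2. The sarcomere list lies at 456 and 491 TPM, whereas the foregut and lung epithelium list lies at 0.865 and 0.2.

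Transcription factors of heart development had a median of 18.7 ± 2.74 TPM, at the edge of the central 95% of random lists, and 28 of 29 were detected. Nkx2-5 (116 ± 1.2) and Gata4 (113 ± 9.14), which act together in cardiac gene activation, were the highest, followed by Tbx20 (51.2 ± 8.1) and Mef2a (47.8 ± 3.73). Tbx1, a factor of the pharyngeal region, was the lowest at 0.67 ± 0.113. Nkx2-5 exceeded Isl1, a marker of second heart field progenitors, 14.6-fold (log2 ratio 3.87, or 3.24 as a ratio of counts), and Hand1 exceeded Hand2 3.28-fold. The median of ventricular markers was 69.2 ± 0.354 TPM, led by Myl2, Myl3, Myh7 and Pln, and that of atrial markers 29.4 ± 3.24, led by Myl7, Myl4, Dkk3 and Stard10. The ventricular factor Irx4 stood 1.94-fold above the atrial factor Nr2f2, a difference that lay within the replicate spread when counts without gene length were used (log2 ratio 0.34). Trabecular genes had a median of 28.3 ± 9.86 TPM, with Nppa, Cited1 (693 ± 25.6), Nppb (237 ± 17.2) and the gap junction gene Gja5 (36.7 ± 16.4) highest, and Nppa was 17.9-fold above Nppb.

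Ion handling and conduction genes lay at a median of 14.4 ± 0.226 TPM, with 24 of 29 detected. Pln (336 ± 7.68), Gja1 (195 ± 20.7), Atp2a2 (188 ± 10.1) and Casq1 (163 ± 12.1) were the highest. The cardiac calcium pump and release channel genes exceeded their skeletal counterparts, Atp2a2 being 41.6-fold above Atp2a1 (log2 ratio 5.38, or 6.40 as a ratio of counts) and Ryr2 202-fold above Ryr1 (7.66, or 4.03 with 1 added to each TPM). The calsequestrin genes went the other way, the skeletal form Casq1 (163 ± 12.1 TPM) standing above the cardiac Casq2 (27.1 ± 3.13), chosen after its values were seen. Gja1 exceeded Gja5 5.59-fold. Cacna1c, of which a processed transcript of 4 exons held 68.2% of TPM, exceeded Cacna1d 9.52-fold (log2 ratio 3.25, or 1.92 as a ratio of counts). Hcn4, the pacemaker channel of the sinus node, was at 2.28 ± 0.283 TPM. It lay 23.9-fold above Hcn2, the lowest of the list at 0.095 ± 0.00707, but the pair ceased to be apart with 1 added to each TPM (log2 ratio 1.58).

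Markers of the other heart cell types, neural crest and glia aside, had medians from 14.4 to 25.2 TPM. Endocardium and endothelium genes had 22.7 ± 3.42 TPM with all 20 detected, led by Plvap (116 ± 12), Egfl7 (112 ± 6.8), Eng (88.7 ± 7.49) and Emcn (51.2 ± 4.3). Cushion and fibroblast mesenchyme genes had 25.2 ± 1.57 with all 22 detected, led by Col3a1 (276 ± 49.2), the proteoglycan gene Vcan (130 ± 3.34), Col1a1 (105 ± 15) and Postn (101 ± 5.74). Epicardial genes had 21.2 ± 0.0849 with all 12 detected, led by Upk3b (76.0 ± 0.0566), Tcf21 (62.0 ± 0.813), Krt19 (44.1 ± 11.0) and the retinoic acid enzyme gene Aldh1a2 (37.6 ± 2.45). Smooth muscle genes had 14.4 ± 1.56, from Acta2 (1234 ± 79.7), Tagln (223 ± 15.8), Cnn1 (178 ± 23.6) and Smtn (51.2 ± 3.27) down to Myh11, the myosin of mature smooth muscle, at 1.15 ± 0.212. Of 7 neural crest and glia genes 2 were detected, with Ets1 the highest at 33.7 ± 7.81, Sox10 at 0.885 ± 0.0636 and Tfap2b at 0.665 ± 0.445. The endothelial and mesenchymal medians lay above the central 95% of random lists, and the epicardial, smooth muscle and neural crest medians did not.

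Of the blood cell lists, the red lineage had the highest level. The erythroid list had a median of 101 ± 9.11 TPM with all 19 measured members detected, its highest being Hbb-y, Hba-a2, Hba-x and Hba-a1. Hbb-y exceeded the other embryonic beta globin Hbb-bh1 4.45-fold and the adult gene Hbb-bs 67.3-fold, while Hba-x and Hba-a1 were not apart (log2 ratio 0.19 ± 0.058), though they were as a ratio of counts (0.78). The other adult beta globin gene, Hbb-bt, chosen after its values were seen, stood above Hbb-bs (2261 ± 332 against 406 ± 80.1 TPM). The alpha globin pair leaves out Hba-a2 (15510 ± 1930), the near-identical copy of Hba-a1. Neither pair therefore gives the balance of embryonic and adult globins. Megakaryocyte genes had a median of 6.19 ± 0.269 TPM, led by Pf4 (83.2 ± 3.17), Ppbp (22.8 ± 2.15), Itga2b (9.05 ± 3.78) and Gp1bb (6.64 ± 0.912). Macrophage genes had 3.18 ± 0.279, led by Lyz2 (53.8 ± 5.81), C1qb (11.7 ± 1.08), Tyrobp (6.74 ± 0.17) and C1qa (6.25 ± 0.332).

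Energy metabolism genes were among the highest lists. Nuclear genes of oxidative phosphorylation had a median of 594 ± 4.84 TPM with all 26 detected, led by Atp5b (3535 ± 213), Cox6b1 (1547 ± 54.7), Cox8a (1312 ± 5.44) and Atp5a1 (1266 ± 108). The 13 mitochondrially encoded mRNAs had 1752 ± 488, the highest being mt-Atp6 (7950 ± 92.9), mt-Atp8 (6683 ± 453), whose short length inflates TPM, mt-Cytb (3718 ± 220) and mt-Nd1 (3408 ± 201). Reads assigned to the nuclear copies of mitochondrial sequence on chromosome 1 may belong to such mRNAs, so their order and median are uncertain. Glycolysis genes had 470 ± 19.2 with all 21 detected, led by Gapdh, Ldha (2406 ± 243), Aldoa (1641 ± 95.3) and Eno1 (1560 ± 55.1), and fatty acid oxidation genes 97.2 ± 10.3 with all 23 detected, led by Etfb (404 ± 18.9), Fabp3 (396 ± 27.0), Etfa (214 ± 7.28) and Hadhb (212 ± 20.2). In pairs of related metabolic genes, Ldha exceeded Ldhb 5.11-fold, Eno1 exceeded Eno3 7.27-fold, Ckb exceeded Ckm 44.5-fold, Hk1 exceeded Hk2 2.64-fold (log2 ratio 1.40, or 2.29 as a ratio of counts) and Pfkl exceeded Pfkm 2.88-fold. The glucose transporter Slc2a1 exceeded the insulin-responsive Slc2a4 20.5-fold, and Cox6a1, Cox7a2 and Cox8a exceeded Cox6a2, Cox7a1 and Cox8b 2.27-, 2.39- and 24.7-fold. As ratios of counts, the log2 ratio of Cox7a2 to Cox7a1 was 2.56 rather than 1.26, and that of Cox8a to Cox8b 5.39 rather than 4.63. The muscle carnitine palmitoyltransferase Cpt1b exceeded the liver form Cpt1a 8.11-fold (log2 ratio of Cpt1a to Cpt1b -3.02, or -2.43 as a ratio of counts). Fabp3 exceeded the adipocyte form Fabp4 199-fold (7.64, or 7.05 with 1 added to each TPM).

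**Figure D2:**
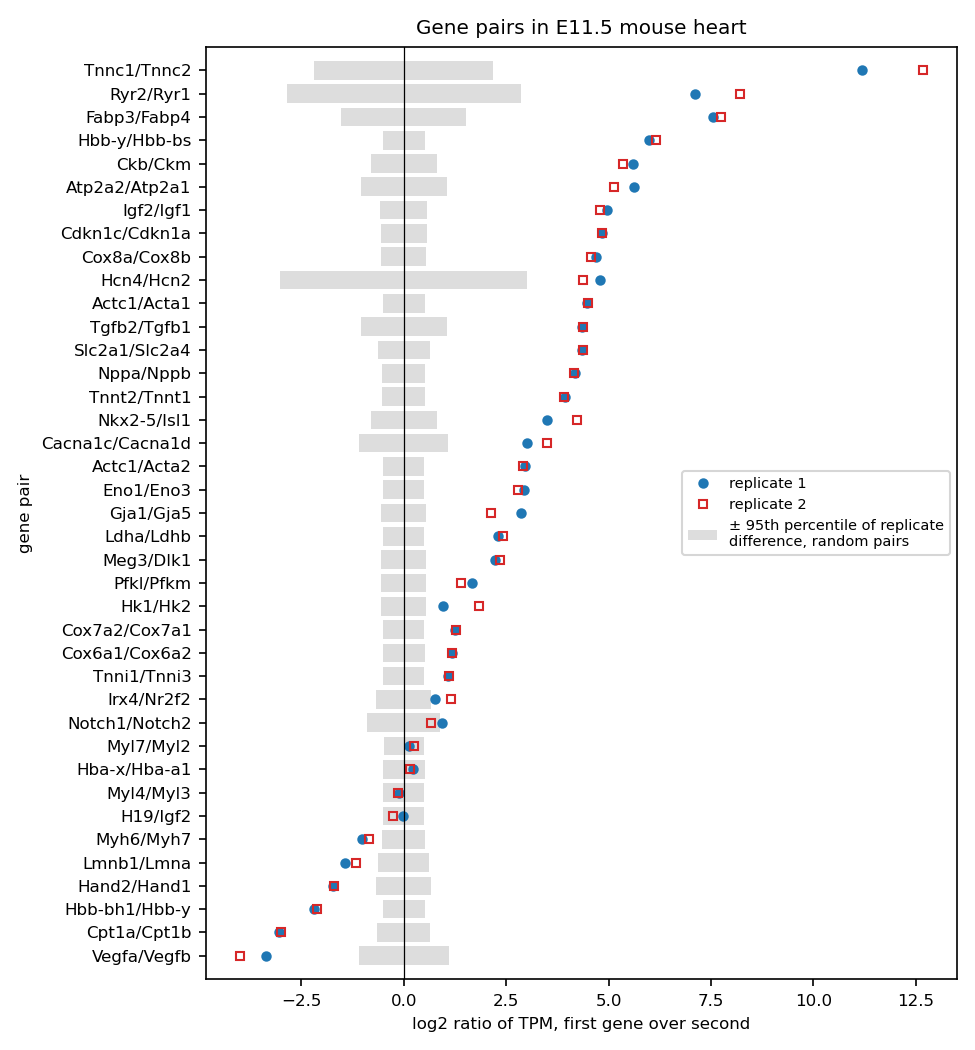
Log2 ratio of TPM of the first gene over the second in each gene pair reported, with filled circles for replicate 1, open squares for replicate 2, and grey bars for the 95th percentile of the replicate difference over matched random pairs on either side of 0. The means beyond their bars range from Vegfa/Vegfb (-3.68) to Tnnc1/Tnnc2 (11.93).

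Proliferation genes were high, the cell cycle list having a median of 112 ± 3.27 TPM with all 26 members detected, led by Ube2c (352 ± 28.7), Cdk1 (279 ± 9.9), Birc5 (190 ± 0.933) and Ccnb1 (180 ± 5.42). The growth-restricting Cdkn1c stood 28.5-fold above Cdkn1a (log2 ratio 4.84, or 5.49 as a ratio of counts), and the lamin gene Lmna 2.47-fold above Lmnb1. Imprinted genes had a median of 92.7 ± 7.16 TPM, with 18 of 20 detected. Mest, Cdkn1c (893 ± 3.83), Igf2 (812 ± 11.5) and H19 (743 ± 91.2) were highest, and Rtl1 lowest at 0.46 ± 0.0707. Igf2 was 29.3-fold above Igf1 (log2 ratio 4.87, or 2.96 as a ratio of counts), Meg3 was 4.87-fold above Dlk1, and H19 and Igf2, neighbours under a shared enhancer, were not apart (-0.13 ± 0.157). Signalling ligands and receptors had a median of 8.6 ± 0.0601 TPM with 30 of 38 detected, led by Igf2, the chemokine gene Cxcl12 (119 ± 5.79), Bmp7 (54.6 ± 8.24) and Tgfb2 (43.1 ± 3.05), and Fgf16 was listed at 0 counts in both libraries. Tgfb2 exceeded Tgfb1 20.6-fold and Vegfb exceeded Vegfa 12.8-fold (log2 ratio of Vegfa to Vegfb -3.68, or -2.25 as a ratio of counts), whereas Notch1 and Notch2 were not apart on average (0.80 ± 0.201, or 0.18 as a ratio of counts). In replicate 1 alone (0.94), and with posterior mean TPM (1.07), they were. Hypoxia response genes had a median of 10.8 ± 0.332 TPM, led by Slc2a1, Bnip3 (230 ± 6.82), Pdk1 (76.8 ± 4.56) and P4ha1 (44.6 ± 6.06). Immediate early and heat shock genes had 6.2 ± 0.513, led by Ier2 (39.9 ± 2.04), Jun (25.1 ± 0.396), Dusp1 (23.6 ± 2.09) and Atf3 (11.5 ± 1.99), with Hspa1b at 0.355 ± 0.00707 and Fosb at 0.085 ± 0.0212.

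Markers of tissues next to the heart had low medians. Skeletal muscle genes had 0.603 ± 0.138 TPM with 4 of 12 detected, Tnni2 (34.6 ± 3.48), Tnnt3 (11.96 ± 0.191), Actn3 (3.63 ± 0.346) and the myogenic factor Myog (2.92 ± 0.247). Neuronal genes had 2.09 ± 0.223 with 7 of 12 detected, led by Tubb3 (10.1 ± 0.0636), Snap25 (8.37 ± 0.764), Elavl4 (5.13 ± 0.552) and Stmn2 (3.85 ± 0.834). Foregut and lung epithelium genes had 0.532 ± 0.47 with 4 of 10 detected, namely Krt18 (30.7 ± 1.27), Krt8 (26.9 ± 3.54), Epcam (3.19 ± 1.29) and Cdh1 (1.11 ± 0.148). Hepatic genes had 2.41 ± 1.59 with 7 of 12 detected. Afp, the fetal serum protein gene, had 59.2 ± 60.7, transferrin Trf 51.6 ± 23.3, Apoa2 25.3 ± 21.6 and Apoa1 13.02 ± 12.4.

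Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, had a median of 3.5 ± 1.22 TPM, led by Hist1h4d (121 ± 16.3), Hist1h2ae (50.8 ± 7.09), Hist1h2bc (43.4 ± 0.396) and Hist1h1e (18.5 ± 3.27). Replication-independent histones had 398 ± 1.09, led by H3f3a (1372 ± 2.91), H2afz (1001 ± 22.8), H3f3b (536 ± 1.58) and H2afv (259 ± 3.75). Among RNAs without a poly(A) tail, with a median of 9.91 ± 1.74 TPM, Rn7s1 and Rn7s2 were followed by Rn7sk (124 ± 14.3), Rpph1 (38.05 ± 0.431) and Rmrp (19.6 ± 3.42). Terc had 2 and 1 counts, and Rnu12, Rprl1, Rprl2 and Rprl3 were listed at 0 in both. The sex-linked list had a median of 8.22 ± 0.396 TPM. Both the Y-linked genes Eif2s3y (25.1 ± 2.35), Ddx3y (11.7 ± 3.31), Kdm5d (7.21 ± 0.905) and Uty (6.62 ± 0.417) and the X-linked RNAs Xist (12.8 ± 5.11) and Tsix (1.59 ± 0.672) were detected in both libraries.

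The most abundant transcript was the same in both libraries for 19 of 22 isoform genes, and in 15 it held over 50% of the gene's TPM in both. Kdr-201 held 99.1% ± 0.481 of Kdr, Actc1-201 nearly all of Actc1, and Nppa has 1 annotated transcript. Tpm1-205 held 90.9% ± 0.0283 of Tpm1 and Tnnt2-207 held 67.0% ± 0.651 of Tnnt2. Tnni3-201 (70.1% ± 0.156), Myl4-202 (71.4% ± 1.54), Mef2a-208 (72.8% ± 6), Pdlim5-205 (68.8% ± 1.58), Cacna1c-218 (68.2% ± 1.34, a processed transcript of 4 exons), Numb-204 (58.6% ± 0.0212) and Slc25a3-206 (56.1% ± 0.0141) also passed 50% in both libraries. Ttn-215, annotated with 12 exons, held 56.9% ± 4.48 of the TPM of the titin gene, and the 192-exon Ttn-201 held 11.6% ± 1.62. A retained-intron transcript of Myl4 and one of Tnni3 took 26.3% ± 1.61 and 26.2% ± 0.177 of their genes. Pkm was divided between Pkm-202 (54.5% ± 1.98) and Pkm-201 (45.5% ± 1.98). No transcript passed 50% in both libraries for Mef2d (51.5% ± 2.67), Ldb3 (49.7% ± 5.54), Mef2c (48.8% ± 2.58), Camk2d (47.5% ± 0.318), Wt1 (39.9% ± 3.13), Fgfr2 (32.2% ± 1.58) or Fn1 (31.6% ± 10.5). The leading transcript of Ldb3, Mef2c and Fn1 differed between the libraries. These shares are model estimates from short reads.

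Most genes had similar levels in both libraries. Across 14501 genes, which are not independent replicates, Pearson's r was 0.984 and Spearman's rho 0.984. The common biological coefficient of variation was 0.139, with a median trended value of 0.373 at mean counts of 10 to 30 and 0.0974 at 1000 to 3000. Of 12084 genes with a mean count of 100 or more, 96.0% lay within 1.5-fold. Spike-in RNAs took 8.43% of counts in replicate 1 (95% Wilson interval 8.42 to 8.44) and 8.61% in replicate 2 (8.60 to 8.62), or 8.52% ± 0.132. The 88 spike-ins above 0 in both correlated with a Pearson's r of 0.992 in log2 TPM and a Spearman's rho of 0.994 in TPM. As TPM they took 16.5% ± 0.732.

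**Figure D3:**
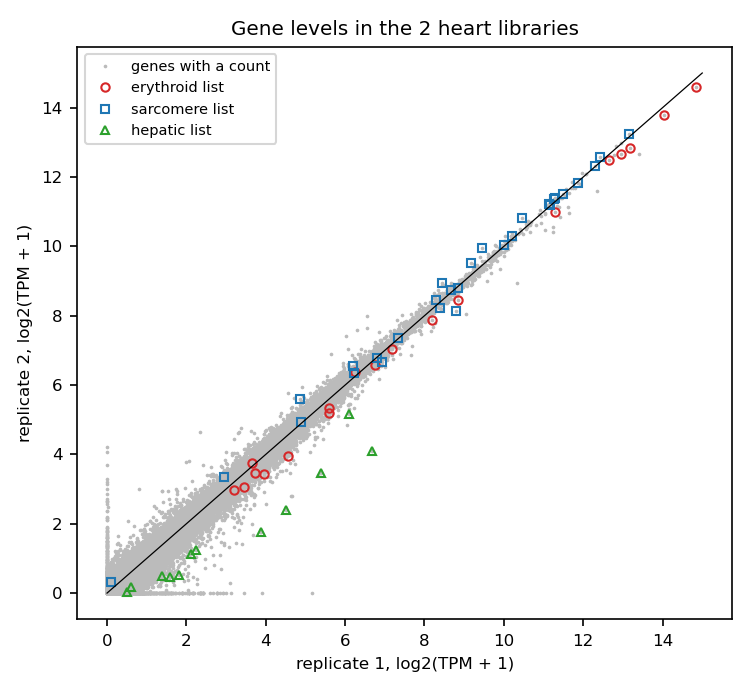
Each point is a gene, with log2(TPM + 1) in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, and the line marks equal values. Sarcomere genes (blue squares) lie on or near the line, 17 of the 19 erythroid genes (red circles) below it, and the 12 hepatic genes (green triangles) all below it.

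Of the gene lists, that of liver genes differed most between the pools, all 12 being higher in replicate 1. Afp (chromosome 5, 90490737 to 90508907) had 102 TPM in replicate 1 and 16.3 in replicate 2, a 6.49-fold difference in scaled counts, and albumin (Alb) was 5.91-fold higher at 13.6 against 2.37 TPM. Of the 12 hepatic genes, 11 were called higher in replicate 1 (largest adjusted p 0.00216, exact binomial test), and likewise 11 when adjusted over the list alone. The exception, Trf, was higher in replicate 1 by less than 2-fold (log2 ratio -0.88). Among called genes with a mean count of 100 or more, the 10 with the largest folds in this direction also included Itih2 (7.16-fold), Fgb (5.81-fold), Apom (5.76-fold), Serpina6 (5.71-fold) and Apoa1 (5.42-fold), all of them genes of plasma proteins made by the liver. Gm26827 (224 and 0 counts), Gm20388 (838 and 17.6 counts) and Tom1 (239 and 9.74 counts) had the largest folds of the 10 (328-, 33.1- and 16.7-fold), with fractional counts that mark shared reads. The largest adjusted p among these 10 genes was 2.7e-28 (exact binomial test). Gm26827 overlaps Chsy1, and Gm20388 spans many other genes.

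In the other direction, the 10 largest folds were those of Bst2 (3.93-fold higher in replicate 2), the cohesin gene Stag3 (3.78-fold), Pla2g15 (2.97-fold), Ipo7 (2.68-fold), Clic1 (2.62-fold), Zadh2 (2.61-fold), Nsg1 (2.58-fold), the protocadherin gene Pcdhgb2 (2.56-fold), Swi5 (2.5-fold) and Trappc3 (2.46-fold). Clic1 and Swi5 were the most abundant of these, at 64.0 and 92.5 TPM in replicate 1 and 169 and 252 TPM in replicate 2. Pcdhgb2 (101.19 and 189.48 counts) and Nsg1 (138.46 and 259.9 counts) had fractional counts, which mark shared reads. In TPM, Pcdhgb2 differed less, at 1.33 in replicate 1 and 2.06 in replicate 2. The largest adjusted p of the 10 was 7.56e-14 (exact binomial test). In all, 779 of 16621 genes were called, 552 higher in replicate 1 and 227 higher in replicate 2. Most had few counts: 51 of the 552 and 29 of the 227 had a mean count of 100 or more, with median mean counts of 27.0 and 23.6. At mean counts of 10 to 30 the trended coefficient of variation (0.373) exceeded the common one (0.139). The test compares 2 libraries and covers counting error alone. With the common dispersion in the edgeR exact test, 228 genes were called, all among the 779. That dispersion was estimated from these same 2 libraries, so the 228 are no independent check of the calls. Protein-coding nuclear genes alone gave 510.

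Most gene lists of the heart itself did not differ between the pools, and 8 of the 31 lay outside the central 95% of random lists. If members varied independently, 1.55 would lie outside by chance. Genes of a list can vary together between any 2 libraries, so the 8 cannot be weighed against that number. Higher in replicate 1 were the hepatic list (median log2 ratio of replicate 2 to replicate 1 of -2.17), foregut and lung epithelium (-0.89), erythroid genes (-0.31), mitochondrially encoded mRNAs (-0.27) and imprinted genes (-0.14). Of the foregut list, 3 of 7 measured members were called, likewise 3 when adjusted over the list alone. They were Nkx2-1, Foxa2 and Foxa1, chosen after their values were seen, and Foxa2 is also on the hepatic list. The foregut list no longer differed with members of 200 or more counts (-0.26). That filter left out the 3 called genes (Nkx2-1 had 74 and 8 counts, Foxa2 30 and 5), so it cannot decide whether they differ. No erythroid gene was called, although 17 of 19 were higher in replicate 1. Higher in replicate 2 were fatty acid oxidation (0.15) and endocardium and endothelium (0.13). The sex-linked list had a median of 0.26 (0.16 and no longer outside as a ratio of TPM), and its members split by chromosome. The log2 ratios of the Y-linked Ddx3y (0.50), Uty (0.37), Eif2s3y (0.31) and Kdm5d (0.22) were above 0. Those of the X-linked Xist (-0.88) and Tsix (-0.93) were below it. Of the 6, 0 were called, each differing by less than 2-fold. Sarcomere (0.05), atrial (0.04), ventricular (-0.01), epicardial (0.02) and cell cycle (0.01) genes lay within the central 95%. Over the 31 lists, members called higher in replicate 1 included 11 hepatic, 3 foregut, and 1 each of the mitochondrial and replication-dependent histone lists, namely mt-Nd3 and Hist1h4c. Those called higher in replicate 2 were Myom2, mt-Nd4l and H1f0. All of these but Myom2 were chosen after their values were seen, and the counts per list were equal when adjusted over the list alone.

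**Figure D4:**
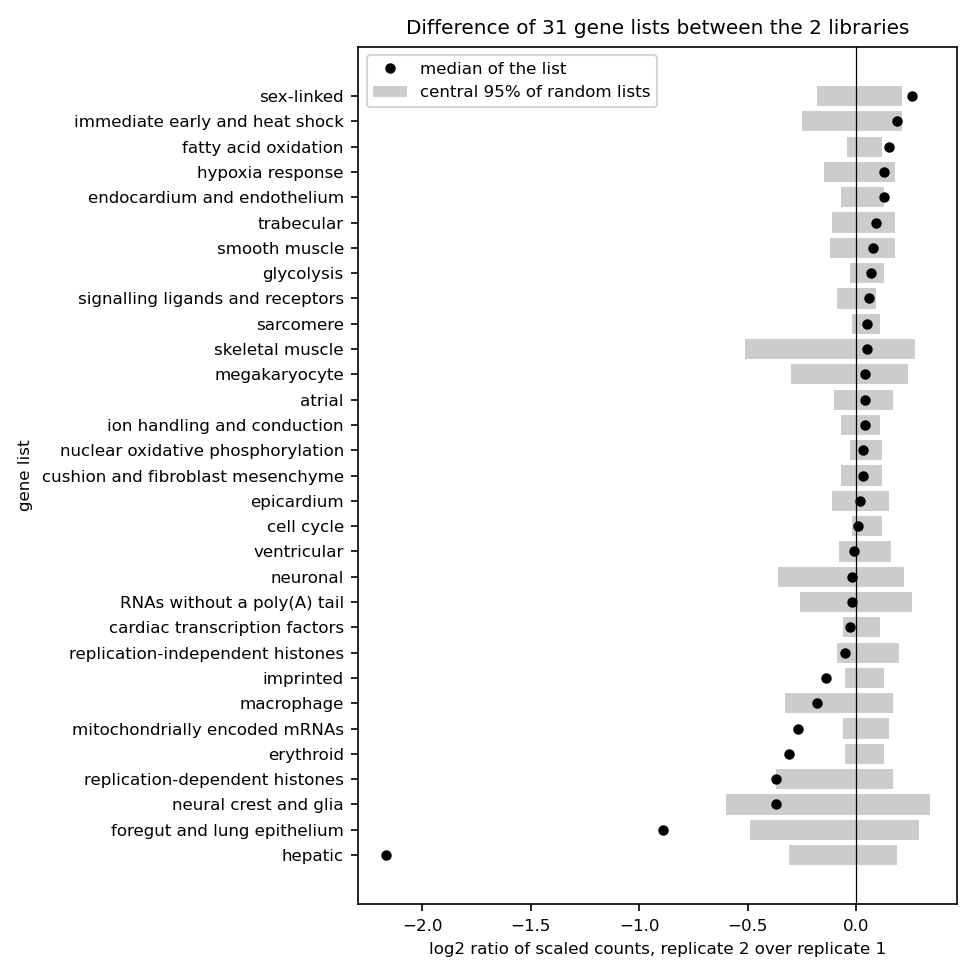
Median log2 ratio of scaled counts (replicate 2 over replicate 1) of the members of each of 31 lists, as black points, with grey bars for the central 95% of 10000 matched random lists. The hepatic list lies at -2.17, far to the left of its bar, while the sarcomere list (0.05) lies within its own.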

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

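The files hold 26248 tRNA rows that entered no comparison. They took 32 expected counts in replicate 1 and 14 in replicate 2, above the 3 counts that a count of 0 allows. The counts lay in 6 and 3 of the rows, with 21 and 12 counts in the row that had most.

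RNAs without a poly(A) tail gave a mixed picture, tested by bounds written in advance. If the libraries held mainly polyadenylated RNA, Rn7sk, Rmrp and Rpph1 were to lie below 10 TPM and replication-dependent histones below 0.1 of the level of replication-independent ones. The histone ratio was 0.00882, far below that bound, whereas Rn7sk (124 TPM), Rpph1 (38.05 TPM) and Rmrp (19.6 TPM) all lay above theirs. The bounds against it, at least 2 of these at 100 TPM or more in both libraries or a histone ratio above a set bound far higher than the value found, were not met either. The values point in opposite directions, so a library of mainly polyadenylated RNA and one of total RNA cannot be told apart here. No biological explanation was tested.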

How the results depend on the processing

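The 2 alternatives that restrict the called genes by type and the correlation without hepatic genes were chosen after seeing the data. The 779 genes called between the libraries became 1498 with a fold of 1.5 (a wider criterion), 228 under an edgeR exact test with the common dispersion (a larger spread), and 510 with protein-coding nuclear genes alone (fewer genes tested). Other scalings gave 778 to 829, no count filter 1141, and leaving out pseudogenes, predicted genes and genes with no symbol 536. Pearson's r of 0.984 became 0.956 with a pseudocount of 0.1, 0.994 with no filter, 0.991 for protein-coding genes and 0.984 (0.9841 against 0.9837) without the hepatic genes. The coefficient of variation of 0.139 became 0.144 with no filter, 0.118 at a mean count of 100 or more and 0.149 with DESeq2 dispersions. The spike-in share of 8.52% of counts was 16.5% of TPM. For correlation, coefficient of variation and spike-in share the cause was not tested. The number of detected genes ranged from 9795 (at 5 TPM) to 16660 (posterior mean TPM), and from 13790 to 14065 with a single library. Lists with a median above the central 95% of random lists numbered 10 to 13, with the cardiac transcription factors near that limit. Pairs apart numbered 33 to 36, lists that differed 7 to 9, and isoform genes with a main transcript over 50% 15 to 18. Of the values of single lists and pairs under alternatives, 312 kept their side of the limit, 6 fell within it, 5 passed it, and 0 called ones changed sign. A count of 0 allows up to 0.0871 CPM in replicate 1 and 0.119 in replicate 2, so lower levels were not detectable at this depth.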

Other observations

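The tests of yolk sac genes, of lincRNA genes and of retained introns, the criteria that decided on blood and on gene length, and all gene groups of the next paragraph were chosen only after the result was seen. Checks of GC content, of mitochondrial content and of hepatic genes picked for the pattern were also run then and decided nothing: removing a trend with GC content moved nothing, the mitochondrial values were undecided, and genes picked for a pattern cannot test it.

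Hox genes were low, and their expression was concentrated in the 3' members of the clusters. The 15 genes of paralogue groups 1 to 5 summed to 18.6 ± 4.09 TPM (n = 2), and 6 of them were detected, Hoxb2 being the highest at 4.37 ± 1.45. The 8 genes of groups 6 to 8 summed to 1.94 ± 0.255 TPM and the 16 genes of groups 9 to 13 to 1.06 ± 0.552, and 0 of either set were at 1 TPM or more in both libraries. Ribosomal protein genes had a median of 653 ± 10.5 TPM, and 18 of 18 were higher in replicate 1 (median log2 ratio -0.13), with 0 called. Genes of gut and septum mesenchyme had a median of 1.99 ± 0.00707 TPM and did not differ as a list (-0.08), although Foxf1, a factor of visceral mesenchyme, was called higher in replicate 1 (438 against 108 counts).

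The genes that differ between the libraries were weighed against a different make-up of the dissected pools, and with 1 group no biological explanation was tested. The erythroid list moved by a median log2 ratio of -0.31 and rho with gene length was 0.14, both between the bounds written in advance for and against blood and length. By the criteria added later the values argue against either as the whole cause: 0 of 19 erythroid genes were called, with quartiles of -0.41 and -0.26, and 765 of the 779 calls held once the trend with length was removed. The 0.05 between the atrial and ventricular lists met the bound written in advance against a different share of atria and ventricles. Members ranged from -0.21 to 0.39 in the atrial list and from -0.39 to 0.31 in the ventricular list. A small difference in share is therefore not excluded. A candidate explanation for part of the pattern is neighbouring liver tissue in the pool of replicate 1, since the hepatic list, of which 7 of 12 genes were detected in both libraries and Foxa2 is also on the foregut list, moved by -2.17, with Afp at 102 against 16.3 TPM and Alb at 13.6 against 2.37 TPM. Yolk sac endoderm, which shares several of these transcripts, cannot be told apart from liver. Of its 7 genes 2 were detected, and the 5 measured ones (median 0.04, range -1.63 to 0.56) included 1 called higher in replicate 1. Hepatic genes, 11 fixed and 11 of 12 picked later for the pattern (median of the 12 -2.52, with Itih3 at 0.05), make up only 22 of the 552 calls higher in replicate 1, most of which had few counts. The foregut and lung epithelium list moved the same way (-0.89, 7 of 7 measured members higher in replicate 1). Its member Nkx2-1, chosen after its values were seen and not on the hepatic list, had 74 against 8 counts. These values therefore do not single out liver among neighbouring tissues.

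Several kinds of noncoding RNA were higher in replicate 1, though not the 7SL copies Rn7s1 and Rn7s2, whose share of TPM there was 0.971 times that in replicate 2. The genes of the ribosomal DNA locus held 1.65 times the share of TPM there, Malat1 1.67 times and mitochondrial ribosomal RNAs 1.38 times, and 8 of 8 measured nuclear-retained long noncoding RNAs, picked for the pattern, were higher (median log2 ratio -0.62), 1 of them called, while Malat1 (-0.87) and the ribosomal DNA genes Gm42418 (-0.81) and Gm26917 (-0.70) differed by less than 2-fold and were not called. Counting noise of genes with few reads is argued against by the median of 357 lincRNA genes, -0.26 (244 higher in replicate 1 and 113 in replicate 2), which lay below the -0.14 to 0.00 of protein-coding genes of similar counts. More nuclear and unspliced RNA in that library may contribute, but the share of retained-intron transcripts was 1.15 times as large, between the bounds for and against it, so this cannot be told apart from other differences in RNA preparation. No biological explanation was tested.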
